A study of Homo sapiens with 9 samples.

How the data were processed

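Total RNA of 9 samples of MDA-MB-231 cells, 3 labelled in each of 3 groups, was measured on Illumina BeadChip arrays with biotin-labelled cRNA. Per the labels' protocols, cells were grown in serum-containing DMEM, transfected with 200 pmol siRNA for 24 h, and RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment and amplified with an Ambion MessageAmp kit. The labels call the reference group control and the design text calls it untreated; a group given a non-targeting siRNA was not analysed here. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

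The deposited signal table holds, per the file headers, an average signal intensity and a detection p-value for each of 47231 probes, with no normalization apparent. A second deposited table by the authors holds log2 values that appear to be quantile normalized between arrays. Its columns share a highest value of 14.9676 and have medians between 6.2302 and 6.232. R 3.1.0 is named per the submitters' processing notes, with no role given; the scanner, its software and the genome build are not given in the sources used here.

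Checks of the files found that control replicate 2 equals the mean of control replicates 1 and 3 in signal (tolerance 1e-06) and in detection p-value (tolerance 1e-05) at 47231 of 47231 probes. Its signals alone carry a second decimal, at 23649 probes. It was therefore left out of the fit, which used 8 arrays (2 controls, 3 WT knockdown, 3 isoform knockdown) in place of the 9 arrays planned. The signals of the 6 knockdown arrays stood in another row order than the probe IDs beside them: the rank correlation with the authors' log2 values of the same arrays lay between -0.00219 and 0.000506 as deposited, against 1 for the controls. Each of the 47231 knockdown rows matched exactly 1 probe of the authors' table by its ranks on the 6 arrays, 0 of them at its own ID, and the rows were put back by that match. The probe identity of all knockdown values thus rests on the authors' log2 table.

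Signals were background-corrected by normexp with detection p-values and an offset of 16, quantile normalized and log2 transformed with neqc in limma 3.58.1 under R 4.3.3. Probes detected (p under 0.05) on at least 3 of the 9 deposited columns were kept, 22467 in all. On each array used, 20295 to 21761 probes were detected, and dimmer probes could not be measured. The median SD across probes was 0.0851 in controls, 0.124 in the WT knockdown and 0.117 in the isoform knockdown, on the log2 scale. Gene symbols came from the platform annotation, in which 30113 probes had 1 symbol, 8 had several and 17110 had none; 12239 genes had a kept probe. Each gene was represented by its probe with the highest mean signal. Gene biotypes and lengths came from the RefSeq gene table of assembly GRCh38.p14; no coordinates were used.

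Group means were fitted with limma (lmFit, contrasts, eBayes; 5 residual and 4.33 prior degrees of freedom) with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Where a probe was detected on none of a group's arrays the fold is a bound ("at least"): the other group's mean was set against the mean over those arrays of the higher of the lowest signal among detected probes and the probe's own. The 30 gene lists, the design, the rule for naming genes and the main alternatives were fixed before the data were examined. The lists cover interferon, NF-kB, stress, cell cycle, metabolic, invasion, signalling, RNA processing and metadherin-linked genes and markers of other cell types. They were tested with camera (preset correlation 0.01, adjusted over the lists) when at least 5 genes were measured, and again with an estimated correlation. The self-contained fry test passed 26, 24 and 22 of 29 lists in the 3 comparisons; it asks whether a list moves, on balance, one way and does not compare it with other genes.

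Named genes are MTDH, the 12 largest rises and falls of each knockdown against control and the 10 of the knockdown comparison among genes past the threshold whose groups did not overlap, and up to 4 members per list with the smallest adjusted p. Groups did not overlap at 67.8%, 62.6% and 45.4% of probes in the 3 comparisons, against 20%, 20% and 10% by chance.

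The fit was tested on simulated data with 200 of 22467 probes changed, independent noise and no normalization step. In the comparison of the WT knockdown with control it recovered 50.7% of changes of 1.5-fold, 76.1% of 2-fold and 100% of 4-fold, with 4 false calls. The isoform knockdown against control gave 50.7%, 73.1% and 100% with 5 false calls, and the comparison of the knockdowns 52.2%, 77.6% and 100% with 5. Far more probes passed in the real data, so these shares and false calls need not hold there. Alternatives tried were other background corrections, scalings, filters, variance models, the authors' log2 values, a replicate block, a 1.5-fold threshold, probe averaging and leaving out each array. The use of all 9 deposited columns was added after seeing the data.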

Results

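RNA from MDA-MB-231 cells, an estrogen receptor-negative line derived from a breast adenocarcinoma, was hybridised to 1-colour Illumina expression arrays. The labels form 3 groups of 3: control cells, cells given an siRNA against wild-type MTDH (called the WT knockdown here), and cells given an siRNA against a spliced isoform of MTDH (the isoform knockdown). MTDH encodes metadherin, a protein that has been linked to metastasis. The study asked how the expression profiles after the 2 siRNAs differ from that of untreated cells, and from each other. Control replicate 2 equalled the mean of control replicates 1 and 3 at all 47231 probes and was not used, which left 2 controls and 3 arrays of each knockdown. Between 20295 and 21761 probes were detected on each of the 8 arrays used, or 43.0% to 46.1% of all probes. The number of arrays limits the precision of every value. No slide or date is given and the controls were tabulated in another row order than the knockdowns. Separate handling and siRNA therefore cannot be told apart in counts compared with control or for genes that changed alike in both knockdowns. Nothing given excludes separate handling of the 2 knockdowns either, so the same limit holds between them. The controls are described as untreated. In comparisons with control, effects of the transfection itself therefore cannot be told apart from effects of lower MTDH. Changes are log2 differences ± SE with Benjamini-Hochberg adjusted p from limma, and levels are mean normalized log2 signal ± SD.

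The targeted gene was lower in both knockdowns. The MTDH probe, ILMN_1810838, had a normalized level of 10.70 ± 0.01 in control cells (n = 2), 9.76 ± 0.16 in the WT knockdown (n = 3) and 9.77 ± 0.09 in the isoform knockdown (n = 3). All 6 knockdown arrays lay between 9.59 and 9.90, below both controls at 10.69 and 10.71. MTDH fell by 0.94 ± 0.11 in the WT knockdown (limma, adjusted p = 0.000123) and by 0.93 ± 0.11 in the isoform knockdown (limma, adjusted p = 0.000285), to 52.2% and 52.3% of the control level. The 2 knockdowns differed by 0.00 ± 0.10 (limma, adjusted p = 0.977). This was the only kept MTDH probe, and the platform annotation assigns it to a RefSeq transcript of MTDH. Whether it also sees the isoform is not known here, and the labels do not give the siRNA sequences.

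**Figure D1:**
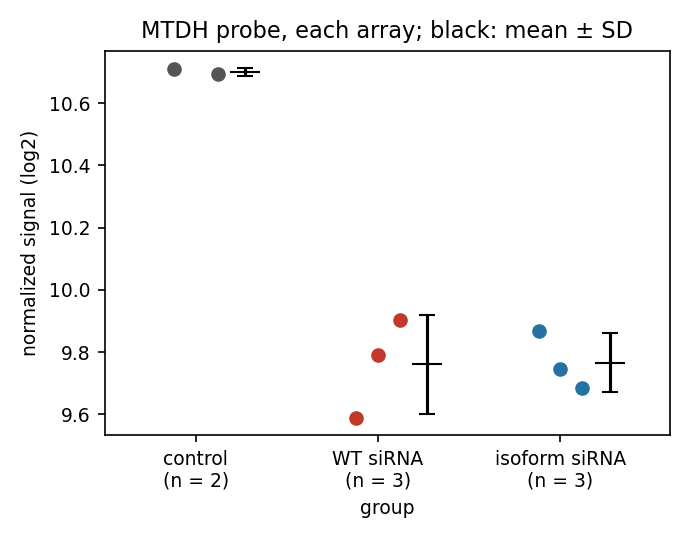
Normalized log2 signal of the MTDH probe (vertical axis) on each array, by group (horizontal axis); black lines show the group mean ± SD. The 2 controls sit at 10.69 and 10.71, and the 6 knockdown arrays sit between 9.59 and 9.90.

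The first comparison asked what differed between the WT knockdown and the untreated control cells. Antiviral genes were among the largest rises: IFIT2 rose by 4.49 ± 0.12, IFIT3 by 3.66 ± 0.09 and OASL by 4.17 ± 0.08, all products of interferon-induced genes that act on viral RNA or its sensing. FERMT3, which encodes an integrin activator best known from blood cells, rose by 4.56 ± 0.11. Among the falls were SNORD13, a small nucleolar RNA, at -4.04 ± 0.22, GMDS, an enzyme of GDP-fucose synthesis, at -2.53 ± 0.11, and FOXQ1, a forkhead transcription factor, at -2.38 ± 0.14. In all, 11576 of 22467 probes passed (limma), 5500 higher and 6076 lower, and 1145 and 978 of these by at least 2-fold. These probes covered 6894 of 12239 genes.

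Several of the largest rises began below background in the controls. ACTA1, skeletal muscle actin, was at least 14.8-fold higher than control. LHX3, a homeobox factor of pituitary and motor neuron development, was at least 12-fold higher, although its other probe did not rise and had a value of -0.38. LAT, a T-cell receptor adaptor, was at least 10.8-fold higher, and BRD8, a bromodomain protein of a histone acetyltransferase complex, at least 7.14-fold higher. The other rises were FOXD4L1 (3.67 ± 0.18), EID3 (3.62 ± 0.15), SNORA71A (3.45 ± 0.10) and GPR83 (3.30 ± 0.17). FOXD4L1 and the small nucleolar RNAs have near-identical copies, so which copy the probe measured is uncertain. Among the falls, the histone methyltransferase SMYD3 was at -2.25 ± 0.14, the histone deacetylase HDAC4 at -2.03 ± 0.13, the collagen COL13A1 at -2.02 ± 0.09 and AGAP1 at -1.96 ± 0.10. The long noncoding RNAs CRNDE and MANCR fell by 1.99 ± 0.17 and 1.92 ± 0.16. The small RNA SNORA79 fell by 2.06 ± 0.20. RPS6KA2 and SCARNA14 ended below background, at least 3.00-fold and 3.18-fold lower.

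Of 29 fixed gene lists tested with camera, 6 were called, all higher. Of 33 measured type I interferon response genes, 24 rose, 3 fell and 6 did not pass (24 and 4 adjusted over the list alone), with a median of 0.90 and an adjusted p = 9.58e-07 (camera); IFIT1 rose by 3.09 ± 0.08. Of 22 NF-kB target genes, 13 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.00113). They included TNFAIP3, a feedback inhibitor of the pathway (2.76 ± 0.08), and SOD2, a mitochondrial superoxide dismutase (2.00 ± 0.11). Of 22 immediate early genes, 15 rose and 3 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.00113), among them the transcription factors EGR1 (2.59 ± 0.12), ATF3 (1.89 ± 0.09) and KLF4 (1.73 ± 0.14). Heat shock proteins rose in 14 of 20 cases and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0025); the HSP90 cochaperone CHORDC1 rose by 1.34 ± 0.11 and HSPA1B by 0.98 ± 0.09. With the inter-gene correlation estimated, adjusted p = 0.0823 for each of these 4 lists. Median scaling ended the heat shock call.

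Of 28 ATF4 and unfolded protein response genes, 14 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.0938 with an estimated correlation). Asparagine synthetase ASNS rose by 2.07 ± 0.09, the stress factor DDIT3 by 1.90 ± 0.10 and PPP1R15A, a regulator of eIF2-alpha phosphorylation, by 1.75 ± 0.09. Of 26 chemokines and cytokines, 13 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.0938 with an estimated correlation), including CCL26 (2.20 ± 0.11), TNFSF10 (1.81 ± 0.10), CCL2 (1.44 ± 0.09) and IL6 (1.37 ± 0.09).

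The other lists were not called in the WT knockdown. Genes linked to metadherin came nearest, with 3 of 23 higher and 14 lower (3 and 14 adjusted over the list alone, camera adjusted p = 0.0618). They include MTDH, the targeted gene, and were not tested without it. Hypoxia and glycolysis followed with 14 of 30 higher and 4 lower (camera adjusted p = 0.0822). In that list ALDOC, a glycolytic aldolase, rose by 2.79 ± 0.09 and the glucose transporter SLC2A1 fell by 1.11 ± 0.09. Mitosis genes were higher in 6 of 33 cases and lower in 14 (adjusted p = 0.406), with DLGAP5 at -1.33 ± 0.11 and BIRC5 at -0.93 ± 0.09. Autophagy genes were higher in 12 of 28 and lower in 4 (adjusted p = 0.117), Wnt pathway genes higher in 4 of 22 and lower in 12 (adjusted p = 0.133), oxidative phosphorylation genes higher in 4 of 32 and lower in 11 (adjusted p = 0.182), and p53 targets higher in 9 of 22 and lower in 3 (adjusted p = 0.186). Mesenchymal markers (1 of 19 higher, 8 lower) and MAPK output genes (7 of 22 higher, 13 lower) both had an adjusted p = 0.211. The list of NRF2 and metal response genes (9 of 23 higher, 5 lower) and the list of splicing factors (13 of 31 higher, 9 lower) had an adjusted p = 0.275. Proteases and inhibitors of invasion (8 of 19 higher, 4 lower) had 0.406 and S phase genes (5 of 32 higher, 12 lower) 0.572 as camera adjusted p.

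The remaining lists had larger adjusted p in the WT knockdown. Epithelial markers were higher in 5 of 16 and lower in 3 (adjusted p = 0.799). Metastasis genes of this line (5 of 16 higher, 5 lower), apoptosis regulators (7 of 28 higher, 7 lower), cholesterol synthesis genes (6 of 25 higher, 7 lower), ribosomal proteins (7 of 39 higher, 10 lower) and TGF-beta targets (8 of 24 higher, 10 lower) each had an adjusted p = 0.801. The small RNA machinery had 4 of 18 higher and 5 lower (adjusted p = 0.906). Among markers of other cell types, luminal markers were higher in 2 of 10 and lower in 2 (adjusted p = 0.906), and leukocyte markers higher in 2 of 10 and lower in 4 (adjusted p = 0.74), with HLA-DRA at -1.06 ± 0.10. Fibroblast markers were higher in 1 of 7 and lower in 3 (adjusted p = 0.854), with a median of 0.14 and a mean of -0.16. Only 2 endothelial markers were measured, too few to test, with ESAM at 0.35 ± 0.09 and ROBO4 at -0.40 ± 0.13. Median scaling in place of quantile normalization took the median change of all probes to -0.19 and gave 2849 probes higher and 7765 lower in place of 5500 and 6076.

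The second comparison asked what differed between the isoform knockdown and the untreated control cells. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 3.62 ± 0.10, and the chemokine CCL26 by 3.13 ± 0.11. The interferon-induced genes OASL, IFIT2 and IFIT3 rose by 3.46 ± 0.08, 3.01 ± 0.12 and 2.86 ± 0.09. Among the falls were SNORD13 at -2.75 ± 0.22, FOXQ1 at -2.28 ± 0.14 and DMBT1, a secreted scavenger receptor, at -2.13 ± 0.10. In all, 9001 of 22467 probes passed (limma), 4285 higher and 4716 lower, with 570 and 299 at least 2-fold, covering 5385 of 12239 genes.

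Further rises were SNORD21 (3.15 ± 0.12), the autophagy gene GABARAPL1 (2.62 ± 0.14), SPANXD, a sperm protein of a family with near-identical copies (2.52 ± 0.09), complement factor CFB (2.49 ± 0.12) and BEX2 (2.44 ± 0.12). ACTA1, below background in controls, was at least 5.25-fold higher. AKR1C2, a steroid-reducing aldo-keto reductase, rose by 2.89 ± 0.14 by its brightest probe while its other probe fell, at -0.35. The other DMBT1 probe did not pass, at -0.21. Further falls were CRNDE (-1.92 ± 0.17), SCARNA14 (-1.74 ± 0.21), the adhesion receptor ADGRF5 (-1.73 ± 0.10), SMYD3 (-1.73 ± 0.14), MANCR (-1.73 ± 0.16), MNS1 (-1.70 ± 0.10), the telomerase RNA TERC (-1.63 ± 0.13), HDAC4 (-1.62 ± 0.13) and RNASEH2B, a subunit of ribonuclease H2 (-1.61 ± 0.10).

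In the isoform knockdown 12 of 29 lists were called. Of 33 interferon response genes, 24 rose, 1 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 6.78e-09). Of 22 NF-kB targets, 13 rose and 4 fell (14 and 4 adjusted over the list alone; adjusted p = 4.62e-05), with TNFAIP3 at 2.06 ± 0.08 and the cytokine IL1B at 1.94 ± 0.10. Of 26 chemokines and cytokines, 15 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 4.62e-05), with CCL2 at 1.71 ± 0.09. Of 22 immediate early genes, 16 rose and 3 fell, also adjusted over the list alone (adjusted p = 8.81e-05), with ATF3 at 2.04 ± 0.09, EGR1 at 1.80 ± 0.12 and the kinase SGK1 at 1.60 ± 0.09. These 4 calls held with an estimated correlation, each at adjusted p = 0.0389, and the other 8 did not.

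Of 30 hypoxia and glycolysis genes, 24 rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p = 2.34e-08; adjusted p = 0.0649 with an estimated correlation). NDRG1 rose by 1.35 ± 0.09, ALDOC by 1.34 ± 0.09, the collagen prolyl hydroxylase P4HA1 by 1.12 ± 0.10 and the enolase ENO2 by 1.04 ± 0.10. Of 33 mitosis genes, 21 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 4.62e-05; adjusted p = 0.0649 with an estimated correlation), among them the kinetochore motor CENPE (-0.90 ± 0.09), cyclin B1 CCNB1 (-0.92 ± 0.11) and the kinase PLK1 (-0.89 ± 0.12). Of 22 Wnt pathway genes, 10 fell and 0 rose (12 and 0 adjusted over the list alone; adjusted p = 0.0133; adjusted p = 0.0888 with an estimated correlation), with cyclin D1 CCND1 at -0.71 ± 0.09 and GSK3B at -0.66 ± 0.10. GSK3B is a kinase that restrains the pathway.

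Of 19 proteases and inhibitors of invasion, 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.0888 with an estimated correlation), with the stromelysin MMP3 at 1.23 ± 0.11 and cathepsin D CTSD at 1.00 ± 0.10. Of 20 heat shock proteins, 9 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0133; adjusted p = 0.0888 with an estimated correlation), with HSPB8 at 1.07 ± 0.11; median scaling ended this call. Of 23 NRF2 and metal response genes, 11 rose and 5 fell (12 and 6 adjusted over the list alone; adjusted p = 0.0168; adjusted p = 0.201 with an estimated correlation), with heme oxygenase HMOX1 at 1.94 ± 0.09 and AKR1C3 at 1.51 ± 0.09. Of 28 ATF4 and unfolded protein response genes, 12 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.0174; adjusted p = 0.0888 with an estimated correlation), with DDIT3 at 2.25 ± 0.10. Of 23 genes linked to metadherin, 2 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.0479; adjusted p = 0.162 with an estimated correlation), with the cell cycle inhibitor CDKN1A at -0.78 ± 0.09 and MTDH itself among them. The metadherin call ended under 7 of 22 alternatives, and the list was not tested without MTDH, the targeted gene.

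Metastasis genes of this line (9 of 16 higher, 5 lower) and autophagy genes (11 of 28 higher, 5 lower) were not called in the isoform knockdown, each with camera adjusted p = 0.0695, but were called under 7 and 4 of 22 alternatives. Also not called were MAPK output (5 of 22 higher, 12 lower; 0.116), oxidative phosphorylation (4 of 32 higher, 12 lower; 0.134) and epithelial markers (5 of 16 higher, 1 lower; 0.176). Cholesterol synthesis genes were higher in 4 of 25 and lower in 11 (adjusted p = 0.185), S phase genes higher in 3 of 32 and lower in 12 (adjusted p = 0.188), TGF-beta targets higher in 9 of 24 and lower in 4 (adjusted p = 0.203), p53 targets higher in 7 of 22 and lower in 5 (adjusted p = 0.425), and ribosomal proteins higher in 7 of 39 and lower in 11 (adjusted p = 0.618). Mesenchymal markers (5 of 19 higher, 5 lower), apoptosis regulators (3 of 28 higher, 7 lower), the small RNA machinery (3 of 18 higher, 4 lower) and splicing factors (9 of 31 higher, 7 lower) had an adjusted p = 0.986. The apoptosis list had a median of -0.11 and a mean of 0.04, and the splicing list a median of -0.07 with the test pointing up. Luminal markers were higher in 1 of 10 and lower in 1 (adjusted p = 0.558), leukocyte markers higher in 1 of 10 and lower in 3 (adjusted p = 0.659), and fibroblast markers higher in 1 of 7 and lower in 1 (adjusted p = 0.649). Of the 2 endothelial markers, ROBO4 fell by 0.39 ± 0.13 and ESAM had a value of 0.04 ± 0.09. Without control replicate 1 the count of probes was 5857 and without control replicate 3 it was 5897, in place of 9001. Median scaling took the median change of all probes to -0.14 and gave 2103 probes higher and 5753 lower in place of 4285 and 4716.

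**Figure D2:**
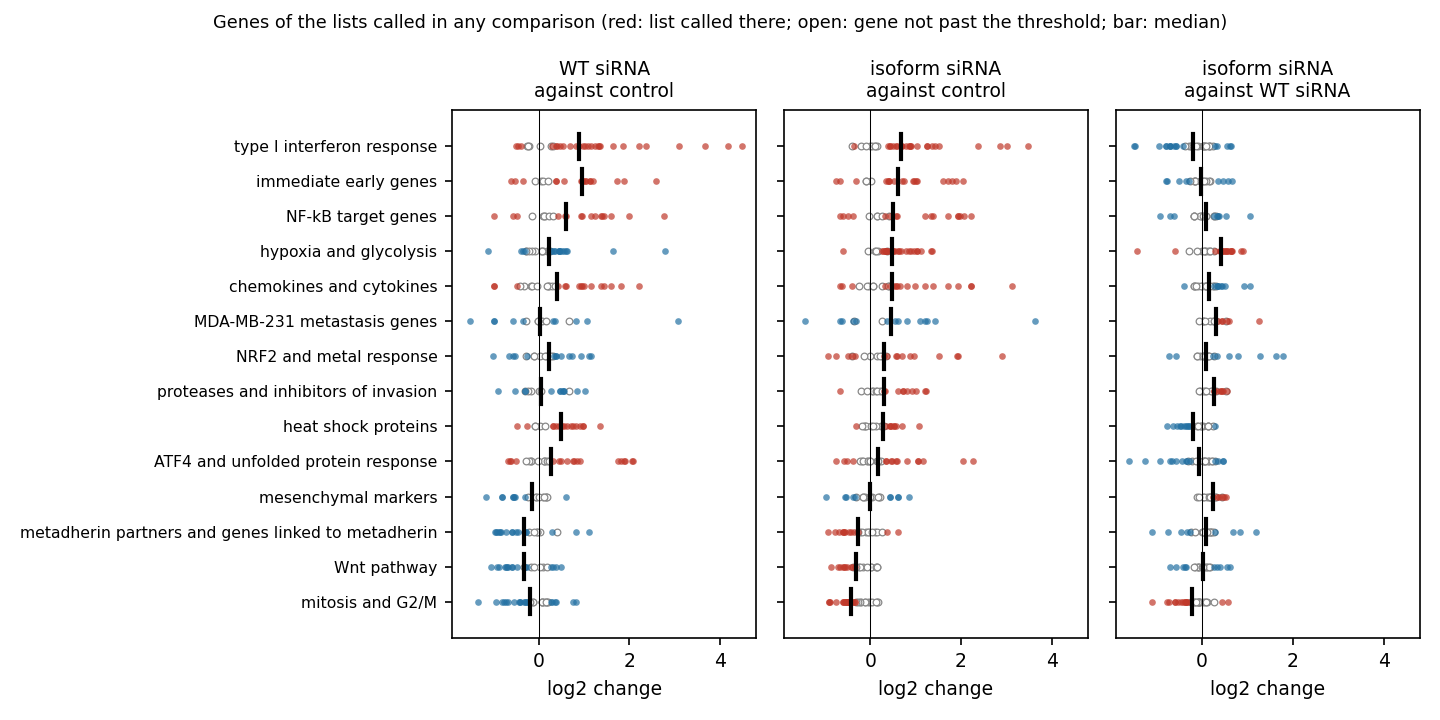
Log2 change (horizontal axes) of the measured genes of each list called in any comparison (vertical axis), for the 3 comparisons. Red points mark a list called in that panel, blue points a list not called there, open points genes not past the threshold and bars the list median, which for interferon genes was 0.90 and 0.68 against control.

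The third comparison set the isoform knockdown against the WT knockdown. The controls did not enter this difference but shared the normalization and the estimate of the spread. SNORD21 was 3.04 ± 0.11 higher in the isoform knockdown, and the aldo-keto reductases AKR1C2, AKR1B10 and AKR1C4 were 1.79 ± 0.12, 1.64 ± 0.15 and 1.44 ± 0.09 higher. FERMT3 and the orphan receptor GPR83 were lower, at -3.29 ± 0.10 and -3.28 ± 0.15. In all, 7399 of 22467 probes passed (limma), 3887 higher and 3512 lower in the isoform knockdown, with 136 and 367 at least 2-fold, covering 4626 genes. With the spread estimated from only the arrays compared, 6906 probes passed.

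Also higher in the isoform knockdown were DPH2, an enzyme of diphthamide synthesis (1.64 ± 0.10), AK6 (1.60 ± 0.10), the transcription factor subunit TAF6 (1.57 ± 0.11), the respiratory complex III subunit UQCRC2 (1.57 ± 0.09), DTX3 (1.49 ± 0.11) and CDK5RAP1 (1.47 ± 0.08). Also lower were SNORA71A (-2.73 ± 0.09), LHX3 (-2.70 ± 0.12), FOXD4L1 (-2.69 ± 0.16), the Y RNA RNY5 (-2.59 ± 0.11) and the signalling adaptor CARD9 (-2.48 ± 0.09). BRD8, VWCE and PNLDC1 were below background in the isoform knockdown, at least 7.08-fold, 5.61-fold and 4.31-fold lower. The other AKR1C2 probe had a difference of -0.06 and that of LHX3 0.07.

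Of the 29 lists, 5 were called in this comparison, and with an estimated correlation each had an adjusted p = 0.169. The count was 9 with no background correction, 8 with normexp and an offset of 50, 8 with the authors' values and 10 with no filter. Of 30 hypoxia and glycolysis genes, 18 were higher in the isoform knockdown and 2 lower (19 and 3 adjusted over the list alone; camera adjusted p = 0.001), with the glycolytic enzymes PGAM1 at 0.90 ± 0.08 and ENO1 at 0.65 ± 0.08, while ALDOC was lower at -1.44 ± 0.08. Mitosis genes were lower in 13 of 33 cases and higher in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.00725), with HMMR at -1.10 ± 0.11, the proliferation marker MKI67 at -0.73 ± 0.08 and the checkpoint kinase TTK at -0.76 ± 0.09. Proteases and inhibitors of invasion, a mixed list, were higher in 8 of 19 and lower in 0 (12 and 0 adjusted over the list alone, camera adjusted p = 0.0073), with TIMP3, a protease inhibitor, at 0.44 ± 0.09. Metastasis genes of this line were higher in 6 of 16 and lower in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.0073), with KYNU at 1.26 ± 0.10 and ANGPTL4 at 0.56 ± 0.09. Mesenchymal markers were higher in 6 of 19 and lower in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.0177), with the cadherin CDH11 at 0.54 ± 0.10. Median scaling ended the mitosis and mesenchymal calls, and a stricter detection filter ended the mesenchymal call.

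Interferon genes (5 of 33 higher, 12 lower in the isoform knockdown), p53 targets (2 of 22 higher, 7 lower), heat shock proteins (1 of 20 higher, 10 lower), NRF2 genes (7 of 23 higher, 2 lower), splicing factors (3 of 31 higher, 11 lower) and chemokines (9 of 26 higher, 1 lower) each had a camera adjusted p = 0.0622 and were not called. Of these, the interferon list was called under 7 of 22 alternatives, the NRF2 list under 5 and the heat shock list under 4. Of single genes in these lists, IFIT2 and the RNA sensor IFIH1 were lower, at -1.48 ± 0.10 and -1.49 ± 0.14, and CCL26 was higher at 0.93 ± 0.10. ATF4 and unfolded protein response genes were higher in 4 of 28 and lower in 10 (adjusted p = 0.257), with ASNS at -1.60 ± 0.08. NF-kB targets (6 of 22 higher, 3 lower), genes linked to metadherin (4 of 23 higher, 5 lower) and immediate early genes (4 of 22 higher, 5 lower) had an adjusted p = 0.674. TGF-beta targets (9 of 24 higher, 5 lower; 0.22), epithelial markers (4 of 16 higher, 2 lower; 0.496), cholesterol synthesis (3 of 25 higher, 6 lower; 0.506), apoptosis (6 of 28 higher, 1 lower; 0.561), S phase (1 of 32 higher, 5 lower; 0.564), oxidative phosphorylation (6 of 32 higher, 2 lower; 0.612) and ribosomal proteins (4 of 39 higher, 4 lower; 0.756) were not called. MAPK output (3 of 22 higher, 4 lower), Wnt (5 of 22 higher, 5 lower) and small RNA machinery (3 of 18 higher, 2 lower) had an adjusted p = 0.825, and autophagy (9 of 28 higher, 6 lower) 0.956. Luminal (2 of 10 higher, 1 lower; 0.732), leukocyte (1 of 10 higher, 2 lower; 0.986) and fibroblast markers (2 of 7 higher, 1 lower; 0.542) were not called. Of the 2 endothelial markers, ESAM was lower and ROBO4 had a value of 0.01 ± 0.12. The median and the test differed in sign for the Wnt (median 0.01), autophagy (-0.04) and leukocyte (-0.01) lists. Median scaling gave 4920 probes, 3045 higher and 1875 lower.

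The changes after the 2 siRNAs were also set against each other. Of the probes tested, 3150 were higher in both knockdowns and 3616 lower in both, where independent lists of the same sizes would share 1049 and 1275, values that leave out the shared controls. IFIT2, IFIT3, OASL, TNFAIP3 and ANGPTL4 rose in both, and SNORD13, FOXQ1, CRNDE, MANCR, SMYD3 and HDAC4 fell in both. Across probes, which are not independent replicates, the 2 log2 changes had a Pearson correlation of 0.765 and a Spearman correlation of 0.759. Unchanged groups simulated 100 times against the same controls gave a mean correlation of 0.601, and 78.9% of probes had changes of the same sign against a simulated 70.5%. The covariance was 0.221 against a simulated 0.0140, a difference of 0.207. With 1 control for each knockdown, so that none was shared, the covariance was 0.210 or 0.209 and the correlation 0.697 or 0.690. A single control is a small reference, and part of the excess in the overlap may come from the shared controls. Among probes higher or lower in both, 66.0% changed more in the WT knockdown.

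**Figure D3:**
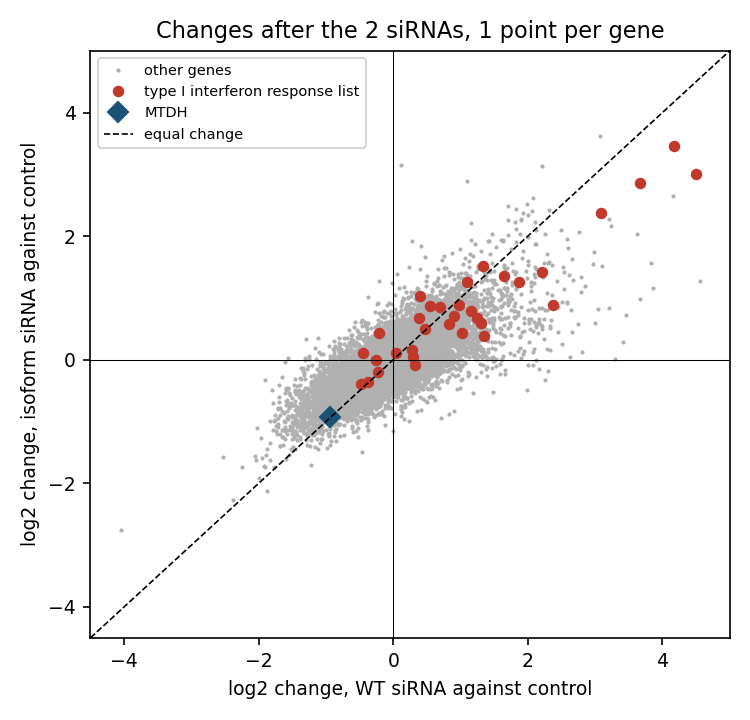
Log2 change of each gene in the WT knockdown (horizontal axis) and in the isoform knockdown (vertical axis), both against the same controls, with interferon response genes in red, MTDH as a blue diamond and equal change as a dashed line. MTDH sits at -0.94 and -0.93, and IFIT2 at 4.49 and 3.01.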

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

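The tests of leukocyte markers and of a response to transfected RNA were chosen only after the result was seen.

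The direction of change differed between the 2 knockdowns at 189 probes, which passed the threshold in opposite directions against control 132 of them the brightest probe of a gene. Several were replication-dependent histone genes: H3C13 was at 0.83 in the WT knockdown and -0.88 in the isoform knockdown, H3C14 at 0.90 and -0.83, and H4C2 at 0.71 and -0.94. The histone genes are near-identical copies, so the single genes are uncertain. How evenly the amplification captured histone RNAs was not tested, so these values need not follow histone mRNA levels. Others were PIGW (1.99 and -0.48), ING3 (1.18 and -0.53) and CLDN1 (-0.46 and 0.55), each by that probe.

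Gene lists also differed between the knockdowns by the camera test of the difference. The median difference, isoform minus WT knockdown, was -0.23 for mitosis genes. It was 0.24 for mesenchymal markers, 0.25 for proteases and inhibitors of invasion, 0.31 for metastasis genes of this line and 0.41 for hypoxia and glycolysis genes. None of these 5 list differences held with an estimated correlation. For the 7399 probes that differed between the knockdowns, 1 of the 10 splits of the 6 arrays, the real one, gave as many, and the highest other split gave 0; with 10 splits a share under 0.05 cannot be reached.

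Interferon response genes rose in both knockdowns, 23 of 33 in both. The labels describe cultures of the MDA-MB-231 line and name no leukocytes. The leukocyte markers could not test for leukocytes as a source, since they went both ways in the WT knockdown. Their median was -0.0645, with 2 of 10 measured markers higher and 4 lower. HLA-DRA and CSF1R, which were measured in the controls as well, were at -1.06 and -1.28. Of the CD68 probes, the brightest fell, at -0.51, and 2 others rose, up to 0.96, and the list's sign turned with the mean over probes (adjusted p = 0.988). A response to transfected RNA is a candidate explanation, since the 23 genes rose with both siRNAs. It cannot be told apart from an effect of lower MTDH, because the controls are described as untreated and a group given a non-targeting siRNA was not analysed here.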

How the results depend on the processing

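All alternatives were fixed in advance except 1 control for each knockdown and the use of all 9 deposited columns, both chosen after seeing the data. The latter gave 13584, 11557 and 8713 probes in the 3 comparisons. MTDH stayed lower and past the threshold in both knockdowns under 20 of 20 alternatives, between -1.28 and -0.85 in the WT knockdown and between -1.22 and -0.89 in the isoform knockdown. Of 377 results for named genes past the threshold, 334 were never lost; over 7708 values, 94 were lost, 32 gained and 7 reversed. A slide block was not run, since no slide is given.

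The estimated correlation left 0 lists called in the WT knockdown, 4 in the isoform knockdown and 0 between the knockdowns. Between the knockdowns 9 lists were called with no background correction, 8 with normexp and an offset of 50, 8 with the authors' values and 10 with no filter. Leaving out an array gave 6 to 6, 11 to 13 and 5 to 6 lists. A 1.5-fold threshold left 6380, 4049 and 2556 probes, fewer by construction, and median scaling left 4920 between the knockdowns. Leaving out an array gave 8945 to 11516 probes for the WT knockdown, 5857 to 9211 for the isoform knockdown and 5920 to 6964 between them; the lowest of the first 2 ranges left 1 control, assumed to vary like the other groups. The correlation of the 2 knockdowns was 0.775 with no background correction, 0.774 with an offset of 50, 0.787 with median scaling, 0.782 with cyclic loess, 0.773 with the authors' values, 0.697 and 0.690 with 1 control for each knockdown, and 0.752 to 0.774 with an array left out. The difference in MTDH between knockdowns, past no threshold, was -0.037 with cyclic loess and -0.0816 to 0.076 with an array left out. The causes were not tested.

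Lists not called were called under some of 22 alternatives. Between the knockdowns these were interferon (7), NRF2 (5), heat shock (4), splicing (2), chemokines (1) and p53 targets (1). In the isoform knockdown they were metastasis genes (7), autophagy (4), MAPK output (1) and oxidative phosphorylation (1), and in the WT knockdown autophagy, hypoxia and genes linked to metadherin (1 each).

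The replicate block gave 10929, 7970 and 6836 probes and changed no list count or MTDH call. Deviations of same-numbered arrays had correlations of -0.028 to 0.058. No shared replicate effect was seen, which does not settle whether the samples were paired.

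ESAM in the isoform knockdown reversed with median scaling (-0.20) and without control replicate 3 (-0.0116, the lowest with an array left out; the highest was 0.0972). ROBO4 between the knockdowns reversed with cyclic loess (-0.0119), array weights (-0.0184) and some arrays left out (-0.0576 to 0.1017). Neither passed the threshold.

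Lists not called in the comparison concerned also changed sign, given here as adjusted p. With median scaling these were apoptosis (0.908) and splicing (0.72) in the isoform knockdown, fibroblast markers in the WT knockdown (0.96), and ribosomal proteins (0.84), leukocyte markers (0.875) and Wnt (0.984) between the knockdowns. With the mean over probes they were apoptosis (0.881), leukocyte markers (0.986) and splicing (0.945) in the isoform knockdown, leukocyte markers in the WT knockdown (0.988), and leukocyte markers (0.768) and Wnt (0.868) between them. Cyclic loess turned ribosomal proteins (0.969 and 0.901) and the small RNA machinery (0.972 and 0.997) in the isoform and WT knockdowns, luminal markers in the WT knockdown (0.997) and leukocyte markers between them (0.995). No filter turned fibroblast (0.89) and luminal markers (0.909) in the WT knockdown. The stricter filter turned mesenchymal markers (0.962) and the small RNA machinery (0.894) in the isoform knockdown and the latter in the WT knockdown (0.921). The replicate block turned leukocyte markers between the knockdowns (0.97), luminal markers in the WT knockdown (0.996) and the small RNA machinery in the isoform knockdown (0.997). That last list also turned with no background correction (0.964), an offset of 50 (0.97) and the authors' values (0.967). With an array left out, sign changes came in the isoform knockdown for apoptosis (0.81 to 0.986), mesenchymal markers (0.864 to 0.995) and the small RNA machinery (0.864 to 0.995). They came in the WT knockdown for luminal markers (0.818 to 0.981) and the small RNA machinery (0.818 to 0.992), and between the knockdowns for autophagy (0.886 to 0.947) and leukocyte markers (0.817 to 0.976). The cause was not tested.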

Other observations

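The families, RNA classes and gene lengths described here were chosen after seeing the data, and the tests of separate handling, genomic DNA, small RNA retention and probe brightness between the knockdowns were chosen only after the result was seen.

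All 5 measured SPANX genes, sperm proteins, were higher in the WT knockdown (median 1.99) and in the isoform knockdown (median 2.38). Of 6 GAGE cancer-testis genes, 5 were higher in the WT knockdown (median 1.04, or 0.49 with no background correction) and 0 in the isoform knockdown (median -0.01, a sign that varied with the background correction), and 5 were lower in the direct comparison. Of 4 FOXD4 genes, 3 were higher in the WT knockdown, 2 in the isoform knockdown and 3 lower in the direct comparison. All 4 aldo-keto reductases of the AKR1B and AKR1C groups were higher in the isoform knockdown (median 1.88), 2 in the WT knockdown (median 0.34; 1 with median scaling, median 0.14, and 3 with cyclic loess) and 4 in the direct comparison (median 1.54). The other AKR1C2 probe fell in the WT knockdown, at -0.29. The SPANX, GAGE and FOXD4 genes have near-identical copies, so single genes are uncertain. Whether the probes tell the AKR1C genes apart was not tested. Of 35 histone genes, 1 rose and 17 fell in the isoform knockdown (median -0.36, or -0.14 with no background correction). In the WT knockdown 11 rose and 8 fell (median 0.03, or -0.02 with cyclic loess), while with median scaling 6 rose and 11 fell (median -0.09). How evenly the amplification captured histone RNAs was not tested.

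Structured noncoding RNAs were higher in the WT knockdown: all 26 measured small nuclear, ribosomal, vault, Y, signal recognition particle and RNase RNAs rose there (median 1.52), 17 rose in the isoform knockdown, and 21 were lower in the isoform than in the WT knockdown (median -0.81). VTRNA1-1 rose by 3.24 and 2.17, RMRP was at 1.49 and, short of the threshold, at -0.02, and the large ribosomal RNAs RNA18SN5 and RNA28SN5 were at 2.10 and 0.28 in the WT knockdown. Background correction or normalization as the whole cause is argued against by the lowest median over 12 settings, 0.925 with no background correction, although median scaling left 21 of 26 past the threshold. Of these settings, only those with another background correction or scaling and the authors' values bear on this cause. Genomic DNA would light up silent probes, and 579 probes gained detection in the WT knockdown while 661 lost it. A gain needed detection on all 3 WT knockdown arrays and a loss on only 2 controls. This favours losses among dim probes, so the counts cannot decide the question. More small RNA kept in the WT knockdown extracts would not raise the large ribosomal RNAs. Of these, RNA18SN5 rose less in the isoform knockdown (0.97), while RNA28SN5 rose alike there (0.28). For the small RNAs such retention may explain the rise and stays open. Of 155 small nucleolar RNA genes, 45.8% were higher in the WT knockdown (median 0.33) and 8.39% lower, the latter between the bounds set for either outcome. How evenly the amplification captured these classes of RNA was not tested.

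Longer genes were lower in both knockdowns, with gene length taken from assembly GRCh38.p14 since the files name no build: over 11462 protein-coding genes, which are not independent replicates, the Spearman correlation of change with length was -0.28 in the WT knockdown and -0.247 in the isoform knockdown. Of genes of 149 kb and more, 85 were higher and 695 lower in the WT knockdown, and 82 and 499 in the isoform knockdown. Processing or probe brightness as the whole cause is argued against by the weakest correlations, -0.238 over 12 settings (with median scaling) and -0.193 within groups of genes by signal, both against control. Of these settings, only those with another background correction or scaling, the authors' values and the stricter filter bear on processing. Separate handling of the controls could produce such a trend and cannot be told apart from the siRNAs: at never-detected probes the highest rank correlation of a control with a knockdown array was 0.41, below the lowest between knockdown arrays, 0.478, though the 2 controls were no closer to each other (0.379). Separate handling of the controls does not explain the part between the knockdowns, where the correlation was 0.155 without any control. There probe brightness stays open, since the correlation was 0.218 and 0.184 among genes of low and middle signal but 0.0445 among those of high signal. Separate handling of the 2 knockdowns stays open too. At never-detected probes the rank correlations were 0.51 to 0.544 within a knockdown group and 0.478 to 0.525 between the 2 groups.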
